A study of Mus musculus with 9 samples.

How the data were processed

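The samples were ulcer skin tissue taken on day 21, per the labels, from animals that the series design describes as rats. The labels give the organism as mouse and the submitters' processing notes name GRCm39, a mouse assembly. All 30560 gene identifiers in the deposited FPKM table are rat Ensembl identifiers, and the last feature on chromosome 1 ends at base 260398790, so rat coordinates were used as the table gives them. The rat genome build is not given in the sources used here. A mouse reference annotation was at hand and was not used. Total RNA was extracted with the RNeasy Plus Mini Kit and libraries were made with the NEBNext Ultra II Directional kit, per the labels. The submitters' processing notes list cutadapt, FastQC, HISAT2 and StringTie without versions or settings.

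The deposited FPKM table, whose unit was given by the authors in its name, held FPKM for 9 libraries (fragments scaled by gene length and library size), and its values are non-negative decimals with totals that differ between libraries. It gave no name for 7162 of its 30560 features (23.4%). The authors' count table held raw read counts of 249 lncRNA genes for the same 9 libraries, per the file headers. It also held the authors' own comparison of diabetic with non-diabetic ulcers, as group means of a signal that the authors made by dividing counts by size factors, a log2 fold change, a p-value and an adjusted p, per the file headers. Neither the authors' test nor their adjustment is named in the sources used here. Because every gene of that table has an unadjusted p under 0.05 in the authors' comparison, it could not serve as the main measurement.

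FPKM values with the same gene name were summed, which gave 28370 features. Features of at least 0.5 FPKM in at least 3 of the 9 libraries were tested, which left 15600, of which 1816 have no gene name and 163 were summed. Values were transformed as log2(FPKM + 1) with no further scaling. The 3 groups were fitted together over all 9 libraries with limma-trend (limma 3.58.1 in R 4.3.3), with group as the term in the model, two-sided contrasts and an F test over the 3 groups. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called. Log2 changes and standard errors (SE) are those of this fit, and group values are means with the standard deviation (SD) over 3 libraries. The p-values of single genes measure the spread between these samples, which the labels number as biological replicates.

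Before the data were examined, 41 gene lists were written for the cell types and processes of healing skin, with 780 genes, of which 675 are in the table. They cover fibrillar collagen and matrix, fibroblast, myofibroblast and smooth muscle, matrix remodelling, basal keratinocyte, differentiated and cornified keratinocyte, wound-edge keratinocyte, hair follicle, sebocyte, adipocyte, skeletal muscle, neutrophil, macrophage, pro-inflammatory macrophage, repair macrophage, dendritic and Langerhans cell, T and NK cell, B and plasma cell, mast cell, endothelial, lymphatic endothelial, Schwann cell, melanocyte, platelet, erythroid, cell proliferation, inflammatory cytokine and chemokine, growth factor, type I interferon response, hypoxia and glycolysis, nuclear-encoded oxidative phosphorylation, fatty acid and lipid synthesis, insulin signalling and glucose handling, oxidative stress response, unfolded protein response, immediate early and heat shock, Wnt and hedgehog signalling, mitochondrially encoded, cytosolic ribosomal protein, replication-dependent histone and sex-linked genes. The 40 lists with at least 3 tested members were tested with camera (limma) at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. At the preset correlation the p of a list treats its members as nearly independent. It takes little account of their shared spread between libraries. Members were also adjusted over the list alone. The level of a list in a library is the mean log2(FPKM + 1) of its members. The epithelial score of a library is that mean over the genes of the basal keratinocyte, cornified keratinocyte and hair follicle lists together. Most of these genes belong to the hair follicle list. The score was defined after the data were seen.

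The rule for named genes was also fixed before the data were examined. For each comparison it takes, among called genes with a name, a higher group mean of at least 1 FPKM and no overlap between the groups, the 8 with the largest rise and the 8 with the largest fall. Where fewer than 5 genes pass, it takes the 5 with the smallest p. Predicted and antisense genes and those with only an identifier or clone name count in the totals but are not named by the rule. From each list described it takes up to 4 members, called members with the highest mean level first and then the other tested members with the highest mean. Genes named outside this rule are said to have been chosen after their values were seen.

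Alternatives fixed in advance were a pseudocount of 0.1, no filter, a filter at 1 FPKM, median-ratio size factors on the FPKM, quantile normalization, no variance trend, sample weights, a fit on only the 6 libraries compared, a replicate block, each feature kept by itself without summing, a minimum absolute log2 change of 1, and each library left out in turn. The count table was tested with edgeR 4.0.16 and DESeq2 1.42.0. Added after the data were seen were the epithelial score as a covariate, non-diabetic replicates 1 and 3 both left out, and edgeR with depths taken from the ratio of counts to FPKM over 81 lncRNA genes with a count of at least 20. With those replicates left out 1 non-diabetic library remained, so calls against it do not measure the spread among non-diabetic ulcers. Unchanged groups sharing the diabetic libraries were simulated 100 times for the comparison of fold changes, and in each draw the share of the 279 highest and 1117 lowest genes with the opposite sign was taken, a share added after the data were seen. In 1 simulation of 15600 genes, 100 were changed by a log2 of 1 and another 100 by a log2 of 2. The limma fit recovered 52% of the former and 97% of the latter, with 5 false calls in the whole simulation. The changed genes were drawn from those with a higher level and a low spread, and the noise was independent between genes. Recovery in the real data can therefore be lower. Figures were drawn with matplotlib 3.10.9.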

Results

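RNA was sequenced from ulcer skin of rats on day 21 in 3 groups of 3 libraries. The groups were non-diabetic ulcers treated with saline, diabetic ulcers treated with saline, and diabetic ulcers treated with platelet-rich plasma (PRP), blood plasma with concentrated platelets. For all 9 libraries the labels give an injection volume of 0.5 ml and injections on days 1, 7, 14 and 21. The last injection day was thus the day of sampling. The measure was FPKM per gene as the authors deposited it, and genes were compared as log2(FPKM + 1). Read totals for the whole transcriptome are not given in the tables used. The FPKM of the non-diabetic libraries summed to 564078, 608331 and 578213 for replicates 1 to 3. Those of the diabetic libraries summed to 574588, 625948 and 676150, and those of the PRP libraries to 728332, 702718 and 708991. From 19591 to 21814 features lay above 0 in a library, and the 10 most abundant features took 38.5% to 52.7% of the FPKM, with 48.8%, 49.2% and 52.7% in the PRP libraries. Depth relative to the mean, from the ratio of deposited counts to FPKM over 81 lncRNA genes, ran from 0.839 to 1.116. In a principal component analysis the first component held 56.6% of the variance. On it non-diabetic replicates 1 and 3 lay at -67.9 and -94.9, and non-diabetic replicate 2 at -1.90. Diabetic libraries lay at 12.5 to 66.8 and PRP libraries at -10.3 to 32.55, so non-diabetic replicate 2 fell within the PRP range. Its Spearman correlation over genes was 0.9162 and 0.8699 with non-diabetic replicates 1 and 3 and 0.9525 with PRP replicate 1. The epithelial score, a mean log2 level of keratinocyte and hair follicle genes, was 3.42, 5.46 and 1.38 in the non-diabetic libraries, 4.46, 6.67 and 6.41 in the diabetic libraries and 5.89, 5.53 and 4.70 in the PRP libraries. Non-diabetic replicates 1 and 3 thus had the lowest scores of the 9 libraries, and the lowest level of each list in the score. Wound-edge keratinocyte genes were not part of it. They stood at 4.16 and 3.11 in these replicates and at 2.57 to 5.35 in the other libraries.

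The first comparison asked how diabetic ulcers differed from non-diabetic ulcers. Lists of connective tissue and macrophage genes fell in diabetic ulcers and the melanocyte list rose in camera with its preset correlation, while no list passed with an estimated correlation (smallest adjusted p = 0.482). Of single genes, 1396 passed. The Wnt modulator Sfrp2 (ENSRNOG00000009465, chromosome 2, 169089517 to 169097063) fell from 79.0 ± 23.3 to 4.92 ± 2.53 FPKM (SD, n = 3 each), a log2 change of -3.79 (SE 0.58, adjusted p = 0.0308). The chemokine gene Cxcl1 (ENSRNOG00000002802, chromosome 14, 17193365 to 17195215) fell from 39.5 ± 31.1 to 1.79 ± 0.446 FPKM (log2 change -3.50), and Ccl2, which attracts monocytes, from 141 ± 72.5 to 16.8 ± 19.6 FPKM (-3.45). The largest fall by the rule for named genes was that of Fam111a (ENSRNOG00000012067, chromosome 1, 209640953 to 209656547), which encodes a serine protease and went from 90.6 ± 37.1 to 2.81 ± 1.32 FPKM (-4.58, SE 1.02, adjusted p = 0.0384). The others were the pentraxin Ptx3 (-4.03), Socs3, a feedback inhibitor of cytokine signalling (-3.88), the immunoglobulin heavy chain gene Ighm (-3.44) and the transcription factor gene Fos (-3.35). Among the rises, the muscle LIM protein gene Csrp3 (ENSRNOG00000014327, chromosome 1, 98528068 to 98546653) went from 23.6 ± 14.9 to 306 ± 113 FPKM (log2 change 3.85, SE 0.70, adjusted p = 0.0308). The Z-disc gene Myoz2 (2.98) and the muscle heat shock gene Hspb7 (2.94) rose with it. The melanin synthesis genes Dct (ENSRNOG00000008671, chromosome 15, 95062003 to 95100836) and Tyrp1 rose by log2 changes of 3.27 and 3.22, Dct from 3.57 ± 3.12 to 37.7 ± 25.8 FPKM. The cornified envelope gene Lce1m (4.31), the amino acid oxidase gene Lao1 (4.25) and the serpin gene Serpina12 (3.30) completed the 8 largest rises. Lce1m and Lao1 were at 32.1 and 8.25 FPKM in non-diabetic replicate 2 and below 1.5 FPKM in the other non-diabetic libraries.

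**Figure D1:**
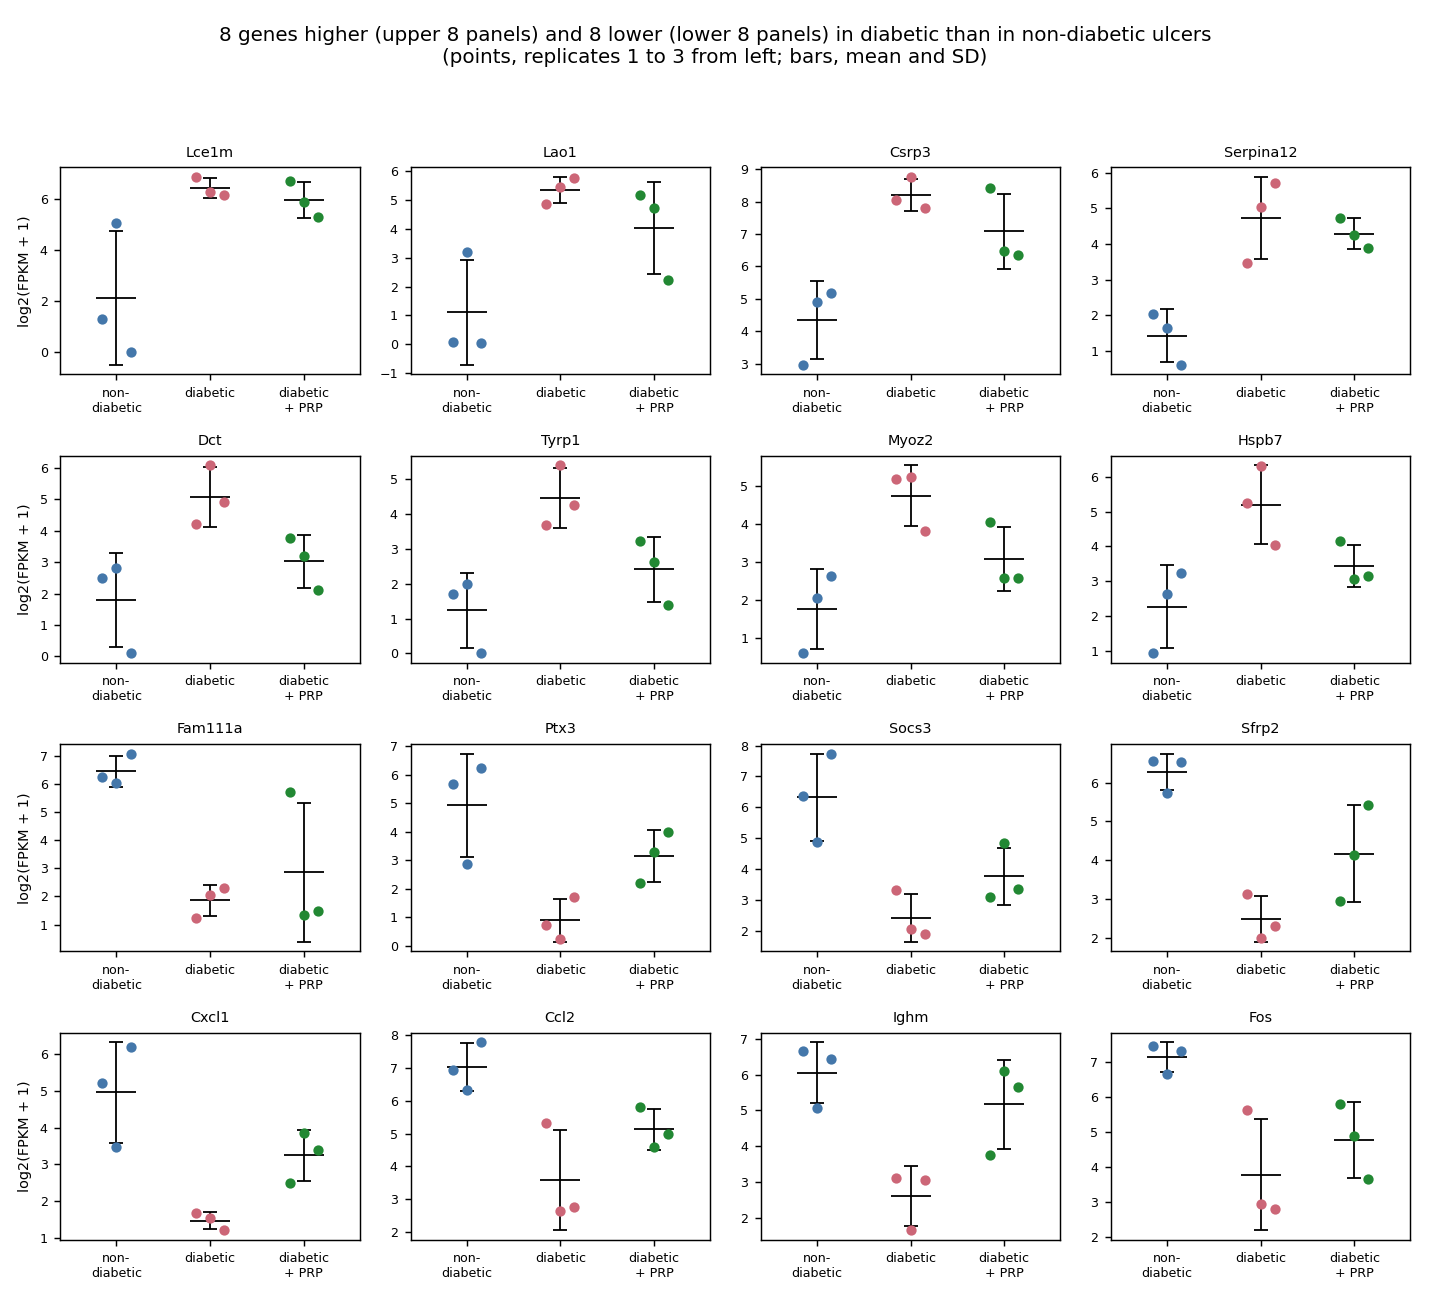
Level of the 16 named genes in each library as log2(FPKM + 1), with 3 libraries per group as points and the mean and SD of each group as bars, on a scale of its own for each gene. In each panel the 3 diabetic libraries lie apart from the 3 non-diabetic ones, and Fam111a is high in PRP replicate 1 (50.9 FPKM) and low in the other PRP libraries (1.56 and 1.83 FPKM).

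In all, 1396 of 15600 tested genes passed in limma, 279 higher and 1117 lower in diabetic ulcers, so that 80.0% of them were lower. Of these, 1289 are protein-coding, and adjusted p-values started at 0.0308. An unadjusted p under 0.05 was reached by 5414 genes, 2448 higher and 2966 lower. In 34.1% of genes the groups did not overlap, where chance gives 10% on average over regroupings of the 6 libraries. Because genes vary together, the share in a single regrouping can lie far from 10%, and its spread was not computed. The count rested on single libraries. It was 0 without non-diabetic replicate 1, non-diabetic replicate 3, diabetic replicate 3 or PRP replicate 2, 2 without diabetic replicate 2 or PRP replicate 1, 374 without PRP replicate 3, 2609 without diabetic replicate 1 and 3501 without non-diabetic replicate 2. It was also 0 with no filter, on only the 6 libraries compared, with the epithelial score as a covariate, and with non-diabetic replicates 1 and 3 both left out, 861 with size factors and 5607 with sample weights. The balance of directions moved too, with 2716 higher and 2891 lower with sample weights, 1515 higher and 1986 lower without non-diabetic replicate 2, and 878 higher and 1731 lower without diabetic replicate 1. The sample weights were 7.495 for non-diabetic replicate 1, 0.482 and 0.827 for non-diabetic replicates 2 and 3, and 2.96 for PRP replicate 2. The non-diabetic level in the weighted fit thus rested mostly on replicate 1.

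Of the 40 gene lists tested, 26 passed in camera for diabetic against non-diabetic ulcers, 11 higher and 15 lower. With an estimated correlation no list passed (smallest adjusted p = 0.482), and none passed in fry (smallest adjusted p = 0.0538).

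The connective tissue lists fell. All 23 fibrillar collagen and matrix genes were lower, with a median log2 change of -1.55 (adjusted p = 1.49e-06, and adjusted p = 0.482 with an estimated correlation). Of these, 5 passed over all genes and 15 adjusted over the list alone. Serpinh1, the collagen chaperone, fell from 874 ± 212 to 220 ± 147 FPKM (SD, n = 3 each), fibronectin (Fn1) from 523 ± 108 to 92.0 ± 41.7 FPKM and fibrillin (Fbn1) from 311 ± 30.8 to 56.4 ± 29.3 FPKM. Of 17 fibroblast genes 16 were lower (median -1.53, adjusted p = 9.07e-06, and 0.482 as the adjusted p with an estimated correlation). In that list 5 passed over all genes and 11 adjusted over the list alone, among them Mfap5 (-2.10), Fstl1 (-1.66) and the PDGF receptor gene Pdgfra, which went from 134 ± 37.8 to 33.7 ± 14.6 FPKM. Matrix remodelling genes had a median of -1.58 (adjusted p = 4.99e-06, and 0.482 as the adjusted p with an estimated correlation), with 18 of 20 lower. In that list 8 fell over all genes and 10 adjusted over the list alone, including the protease gene Mmp14 (-1.87) and the metalloproteinase inhibitor gene Timp1, which went from 295 ± 220 to 33.3 ± 7.75 FPKM. All 16 endothelial genes were lower (median -0.92, adjusted p = 1.22e-05, and 0.482 as the adjusted p with an estimated correlation), with 3 passing over all genes and 9 adjusted over the list alone, such as Tie1 (-1.40) and Eng (-1.36). Beside these lists, the epithelial score averaged higher in the diabetic libraries. With non-diabetic replicates 1 and 3 left out, 1 non-diabetic library remained, so the spread among non-diabetic ulcers could not be judged. The medians were then -1.24 for matrix, -1.45 for fibroblast, -0.79 for matrix remodelling and -0.69 for endothelial genes. With the epithelial score as a covariate the medians were -1.04, -1.12, -0.83 and -0.31, and all 4 lists passed, the endothelial list with an adjusted p of 0.0157. The fibroblast median was -0.98 without diabetic replicate 2.

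Immune lists fell as well. All 18 macrophage genes were lower in diabetic ulcers (median -1.60, adjusted p = 4.78e-07, and 0.482 as the adjusted p with an estimated correlation). In that list 10 passed over all genes and 14 adjusted over the list alone. Lysozyme (Lyz2) fell from 1186 ± 335 to 265 ± 197 FPKM, the complement gene C1qa from 323 ± 29.9 to 117 ± 79.9 FPKM and the receptor gene Csf1r from 92.8 ± 11.8 to 32.4 ± 22.7 FPKM. The pro-inflammatory macrophage list (median -1.37, adjusted p = 6.84e-05) and the repair macrophage list (median -1.48, adjusted p = 0.000219) both fell, each with an adjusted p of 0.482 with an estimated correlation. In the former 4 of 12 genes fell and 6 adjusted over the list alone, among them Irf5 (-1.23) and Cd86 (-1.50). In the latter 5 of 13 fell and 6 adjusted over the list alone, among them Arg1 (-2.45) and Stab1 (-1.79). The B and plasma cell list (median -0.75, adjusted p = 0.000219, and 0.482 as the adjusted p with an estimated correlation) had all 11 genes lower, with 3 passing and 6 adjusted over the list alone, led by Ighm and the joining chain gene Jchain (-3.10). Without non-diabetic replicates 1 and 3, with 1 non-diabetic library left, the medians were -1.50 for macrophage and -0.54 for pro-inflammatory macrophage genes. They were -0.92 for repair macrophage and -0.39 for B and plasma cell genes. With the epithelial covariate they were -0.73 for pro-inflammatory macrophage, -0.92 for repair macrophage and -0.45 for B and plasma cell genes, and these lists passed. At a pseudocount of 0.1 they were -2.05 for pro-inflammatory macrophage and -2.37 for B and plasma cell genes.

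Of the next immune lists, 3 no longer passed without the 2 non-diabetic libraries with low epithelial scores. Inflammatory cytokine and chemokine genes had a median of -1.77 (19 of 21 lower, adjusted p = 8.76e-05), with 3 passing, Ccl2, Cxcl1 and Ccl7 (-3.13), and 5 adjusted over the list alone. T and NK cell genes had a median of -0.76 (12 of 13 lower, adjusted p = 0.00134), with 1 passing, Cd8a (-2.32), and 3 adjusted over the list alone. Neutrophil genes had a median of -1.67 (all 15 lower, adjusted p = 0.00136), with 1 passing, Clec4d (-3.32), and 0 adjusted over the list alone. Each of the 3 lists had an adjusted p of 0.482 with an estimated correlation. Without non-diabetic replicates 1 and 3 their medians were -0.17, -0.22 and 0.03 (adjusted p = 0.301, 0.236 and 0.824), and with the epithelial score as a covariate none of them passed (adjusted p = 0.108, 0.366 and 0.411). Without non-diabetic replicate 3 alone, cytokine genes had a median of -0.85 and neutrophil genes of -0.87, and both lists passed. At a pseudocount of 0.1 the medians were -1.53 for T and NK cell and -2.65 for neutrophil genes. The platelet list fell with 4 genes (median -1.17, adjusted p = 0.0108, and 0.482 as the adjusted p with an estimated correlation), with 0 passing over all genes and 4 adjusted over the list alone, and its adjusted p was 0.0739 with the epithelial covariate. Its median was -0.75 without non-diabetic replicates 1 and 3 and -1.86 at a pseudocount of 0.1. Its member with the highest level, the chemokine gene Pf4, stood at 44.9 ± 1.53 FPKM in non-diabetic and 17.6 ± 16.5 FPKM in diabetic ulcers (adjusted p = 0.0811).

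Lists of epithelium, skin appendages, muscle and pigment cells rose. The 13 differentiated and cornified keratinocyte genes were all higher (median 2.63, adjusted p = 9.19e-05), with 1 passing, Lce1m, and 8 adjusted over the list alone. Krt10 stood at 278 ± 240 FPKM in non-diabetic and 897 ± 301 FPKM in diabetic ulcers, a log2 change of 2.63 that did not pass (adjusted p = 0.132). All 12 basal keratinocyte genes were higher (median 0.98, adjusted p = 0.00331), as were all 29 hair follicle genes (median 3.43, adjusted p = 5.49e-06), with 0 passing in either list over all genes and 0 adjusted over the list alone. The hair root sheath keratin Krt71 stood at 238 ± 346 and 1149 ± 864 FPKM (adjusted p = 0.153). All 12 sebocyte genes were higher (median 1.84, adjusted p = 0.000218), with 0 passing and 10 adjusted over the list alone. Of 15 adipocyte genes 13 were higher (median 0.77, adjusted p = 0.00955), with 0 passing and 0 adjusted over the list alone. Each of these 5 lists had an adjusted p of 0.482 with an estimated correlation. Hair follicle genes had a median of 0.18 (adjusted p = 0.506) without non-diabetic replicates 1 and 3. The epithelial covariate is made of the hair follicle, basal and cornified keratinocyte lists and takes up their shared change by construction. It therefore does not test them. With it their medians were -0.36, 0.19 and 0.68, in that order. Adipocyte genes did not pass without those 2 libraries or with the covariate (adjusted p = 0.320 and 0.0854). Without non-diabetic replicates 1 and 3, with 1 non-diabetic library left, the medians were 1.11 for cornified keratinocyte, 0.36 for basal keratinocyte and 0.43 for sebocyte genes. With the covariate the sebocyte median was 0.60, and the list passed. Without non-diabetic replicate 3 alone the medians were 1.94 for hair follicle, 1.25 for cornified keratinocyte and 0.48 for basal keratinocyte genes, and without non-diabetic replicate 2 that of adipocyte genes was 1.17. At a pseudocount of 0.1 they were 2.93 for sebocyte and 1.41 for adipocyte genes.

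All 18 skeletal muscle genes were higher in diabetic ulcers (median 2.45, adjusted p = 9.59e-05, and 0.482 as the adjusted p with an estimated correlation), with 0 passing over all genes and 11 adjusted over the list alone. The myosin light chain gene Mylpf stood at 721 ± 616 and 3029 ± 1916 FPKM (adjusted p = 0.0955). The median was 1.40 without non-diabetic replicate 1 and 0.94 without non-diabetic replicates 1 and 3. Of 9 melanocyte genes 8 were higher (median 1.89, adjusted p = 0.000156, and 0.482 as the adjusted p with an estimated correlation), with 5 passing and 7 adjusted over the list alone. Beside Dct and Tyrp1, the tyrosinase gene Tyr rose from 0.390 ± 0.351 to 9.003 ± 6.06 FPKM and the melanosome gene Oca2 from 0.134 ± 0.116 to 2.15 ± 1.52 FPKM. The melanocyte median was 1.21 without non-diabetic replicates 1 and 3, with 1 non-diabetic library left. With the epithelial covariate the melanocyte median was 0.92, and the list passed. The melanocyte median was 3.21 at a pseudocount of 0.1.

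Metabolic lists rose as well. Of 27 nuclear-encoded oxidative phosphorylation genes 25 were higher (median 0.58, adjusted p = 1.49e-06), with 6 passing and 17 adjusted over the list alone, among them the complex I gene Ndufa6 (0.97) and the ATP synthase gene Atp5f1b (0.83). Fatty acid and lipid synthesis genes had a median of 0.78 (17 of 21 higher, adjusted p = 0.000287), with 0 passing and 12 adjusted over the list alone. All 12 mitochondrially encoded genes (median 0.59, adjusted p = 0.00475) and 24 of 26 cytosolic ribosomal protein genes (median 0.47, adjusted p = 0.000817) were higher, with 0 passing in either list over all genes and 0 adjusted over the list alone. Lower were the type I interferon response (median -0.49, 18 of 20 lower, adjusted p = 0.00435), with Stat2 (-0.53) and Oasl2 (-1.14) passing and 2 adjusted over the list alone, and the immediate early and heat shock list (median -0.73, 15 of 19 lower, adjusted p = 0.0175), with 5 passing and 6 adjusted over the list alone, among them Fos and Junb (-1.38). Growth factor genes had a median of -0.42 (21 of 28 lower, adjusted p = 0.0332), with Bmp2 higher (1.22) and Hgf lower (-1.07), and 2 higher and 5 lower adjusted over the list alone. Each of these 7 lists had an adjusted p of 0.482 with an estimated correlation. Without non-diabetic replicates 1 and 3, with 1 non-diabetic library left, the medians of oxidative phosphorylation and lipid synthesis genes were 0.33 and 0.35. With the epithelial covariate they were 0.37 and 0.33, and both lists passed. The median of growth factors was -0.66 without non-diabetic replicate 2, and that of ribosomal protein genes 0.31 without diabetic replicate 3. Single libraries decided 4 of these calls, since growth factors did not pass without diabetic replicate 2 (adjusted p = 0.0962) or 3 (0.128), interferon genes without diabetic replicate 2 (0.225), immediate early genes without diabetic replicate 3 (0.0744) and mitochondrially encoded genes without non-diabetic replicate 2 (0.0674). Ribosomal protein genes did not pass under quantile normalization (adjusted p = 0.218), and growth factor, immediate early and ribosomal protein genes passed neither without non-diabetic replicates 1 and 3 (adjusted p = 0.236, 0.0903 and 0.226) nor with the epithelial covariate (0.534, 0.0981 and 0.0564).

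**Figure D2:**
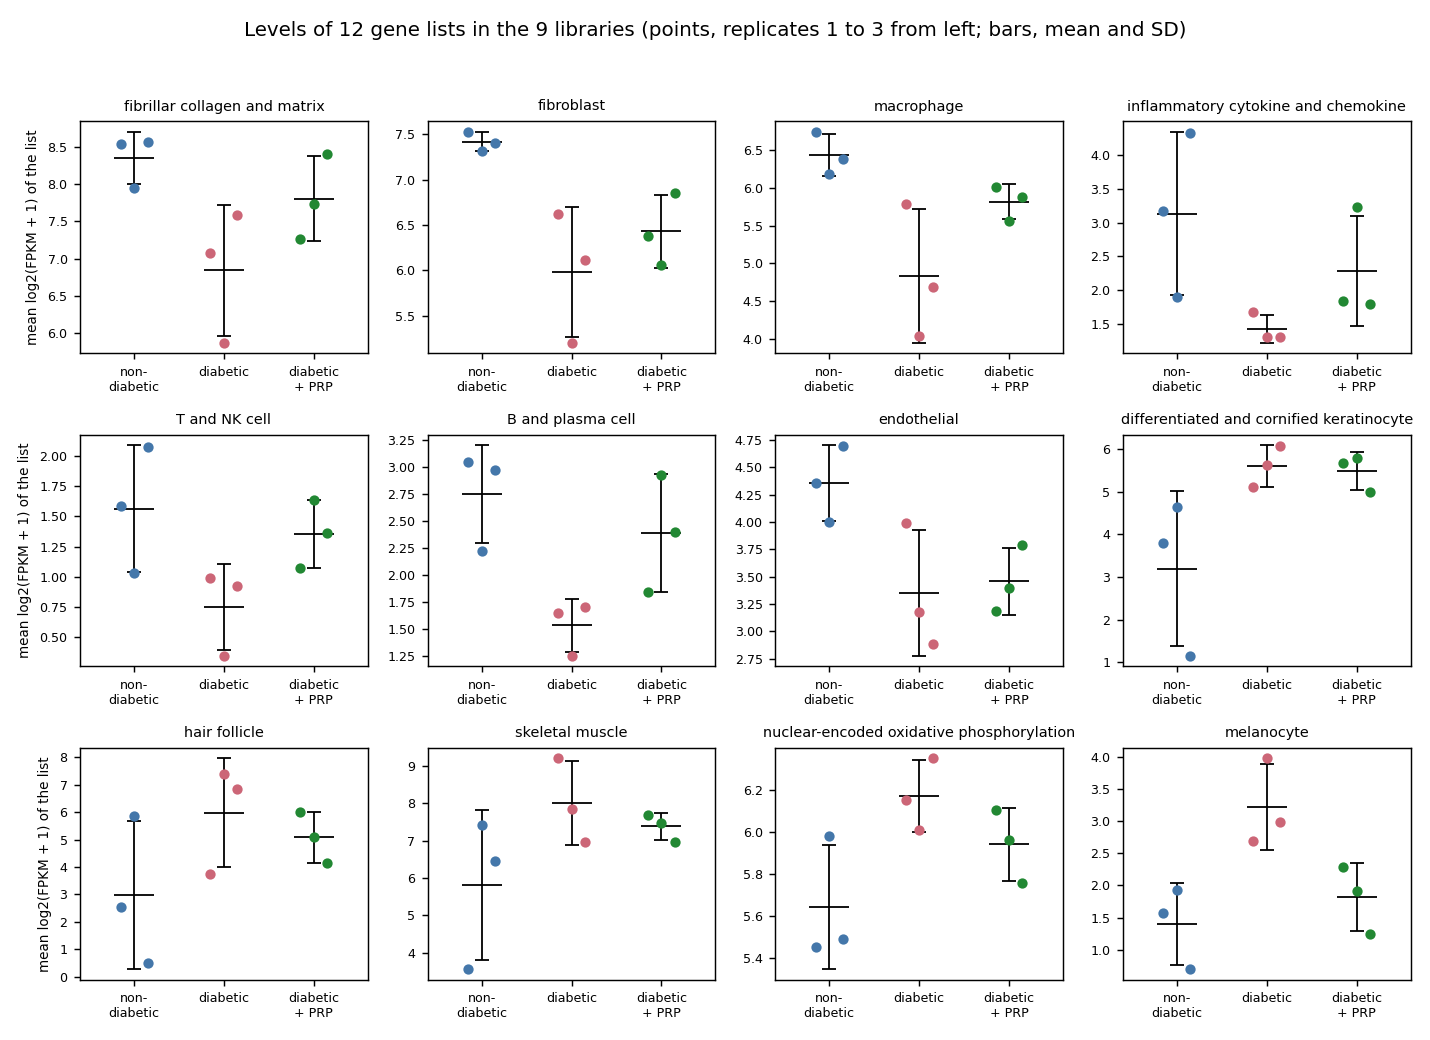
Mean log2(FPKM + 1) of 12 gene lists in each library, with 3 libraries per group as points and the mean and SD of each group as bars, on a scale of its own for each list. Matrix genes average 8.35 in non-diabetic, 6.85 in diabetic and 7.80 in PRP libraries, and melanocyte genes 1.40, 3.22 and 1.81.

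The second comparison asked what PRP changed in diabetic ulcers. No single gene passed. In camera with its preset correlation, lists of matrix, macrophage and lymphocyte genes rose and the melanocyte list fell, while no list passed with an estimated correlation (smallest adjusted p = 0.624). In limma 0 genes passed (smallest adjusted p = 0.0805), and edgeR and DESeq2 on the deposited lncRNA counts also called 0. An unadjusted p under 0.05 was reached by 1021 genes, 621 higher and 400 lower with PRP. The groups did not overlap in 11.4% of genes, where chance gives 10% on average, with a spread that was not computed. The 5 genes with the smallest p among those the rule admits, none of them passing, were the microRNA gene rno-mir-450a, the Fc receptor gene Fcgr2a, the myeloid receptor gene Cd300lf, the dynamin gene Dnm3 and Tcp11l2. The level of rno-mir-450a (ENSRNOG00000069292, chromosome X, 132801380 to 132801470) was 0.195 ± 0.104 FPKM in diabetic and 1.73 ± 0.115 FPKM in PRP ulcers (SD, n = 3 each), a log2 change of 1.19 (SE 0.15, adjusted p = 0.188). That of Fcgr2a (ENSRNOG00000049422, chromosome 13, 83280784 to 83295967) was 23.9 ± 8.13 and 72.9 ± 10.2 FPKM (1.61, adjusted p = 0.713). Cd300lf (1.05), Dnm3 (0.78) and Tcp11l2 (-0.80) had the same adjusted p. With no filter 1 gene was called, AC096311.2, and with size factors another, AC105648.6 (adjusted p = 0.0494).

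With PRP, 16 of the 40 lists passed in camera, 14 higher and 2 lower than in untreated diabetic ulcers. With an estimated correlation no list passed (smallest adjusted p = 0.624), and none passed in fry (smallest adjusted p = 0.459). In every list below, 0 members passed over all genes. Fibrillar collagen and matrix genes had a median log2 change of 1.07 (22 of 23 higher, adjusted p = 2.71e-09), and matrix remodelling genes of 0.90 (17 of 20 higher, adjusted p = 1.01e-06), each with 0 adjusted over the list alone. The collagen gene Col1a1 stood at 1741 ± 1499 FPKM in diabetic and 3048 ± 1433 FPKM in PRP ulcers, and the macrophage elastase gene Mmp12 at 32.5 ± 36.6 and 162 ± 40.6 FPKM. Macrophage genes had a median of 0.77 (17 of 18 higher, adjusted p = 1.08e-08, 0 adjusted over the list alone), with Lyz2 at 265 ± 197 and 784 ± 339 FPKM. T and NK cell genes had a median of 0.52 (all 13 higher, adjusted p = 1.62e-06, 0 adjusted over the list alone), and B and plasma cell genes of 0.47 (10 of 11 higher, adjusted p = 2.34e-06, 3 adjusted over the list alone). Ighm stood at 5.73 ± 3.10 and 43.3 ± 28.2 FPKM and Jchain at 5.32 ± 3.26 and 38.0 ± 22.2 FPKM. All 21 cytokine and chemokine genes were higher (median 0.54, adjusted p = 2.22e-05, 0 adjusted over the list alone), with Ccl2 at 16.8 ± 19.6 and 36.7 ± 17.0 FPKM. All 9 melanocyte genes were lower (median -1.32, adjusted p = 1.46e-07, 7 adjusted over the list alone), with Dct at 37.7 ± 25.8 and 8.06 ± 4.73 FPKM. These 7 lists passed in all 16 alternatives run on lists with the preset correlation, but the size of the change rested on single libraries and settings. The matrix median was 0.46 without diabetic replicate 2 and 0.67 without PRP replicate 3, and the macrophage median was 1.24 without diabetic replicate 1. Without PRP replicate 2 the median was 0.31 for T and NK cell genes and 0.21 for cytokines (adjusted p = 0.0363). At a pseudocount of 0.1 it was 1.22 for T and NK cell, 1.69 for B and plasma cell and 1.19 for cytokine genes, and with a filter at 1 FPKM it was 1.02 for T and NK cell genes. With an estimated correlation the adjusted p was 0.641 for cytokines and 0.624 for the other 6.

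The other 9 lists that passed with PRP depended on single libraries, and each is given with its adjusted p at the preset correlation and then its adjusted p with an estimated correlation. Neutrophil genes had a median of 0.68 (14 of 15 higher, adjusted p = 0.00155 and 0.684), with S100a9 at 59.3 ± 75.2 and 1418 ± 1876 FPKM, and did not pass without PRP replicate 2 (adjusted p = 0.204). Wound-edge keratinocyte genes had a median of 0.88 (11 of 15 higher, adjusted p = 0.00284 and 0.684), with Krt6a at 168 ± 121 and 796 ± 663 FPKM, and did not pass without diabetic replicate 1 (0.298) or PRP replicate 2 (0.191). Fibroblast genes had a median of 0.43 (13 of 17 higher, adjusted p = 0.00298 and 0.684) and did not pass without diabetic replicate 2 (0.656) or PRP replicate 3 (0.207). The pro-inflammatory macrophage list had a median of 0.44 (11 of 12 higher, adjusted p = 0.00257 and 0.641) and did not pass without diabetic replicate 2 (0.0510). Repair macrophage genes also had a median of 0.44 (9 of 13 higher, adjusted p = 0.00419 and 0.641) and did not pass without diabetic replicate 2 (0.210) or 3 (0.0949). Dendritic and Langerhans cell genes had a median of 0.27 (7 of 9 higher, adjusted p = 0.00943 and 0.624) and did not pass without diabetic replicate 2 (0.123) or PRP replicate 3 (0.138). Schwann cell genes had a median of 0.33 (9 of 11 higher, adjusted p = 0.00731 and 0.641) and did not pass without diabetic replicate 2 (0.123) or PRP replicate 1 (0.0636). Unfolded protein response genes had a median of 0.17 (14 of 18 higher, adjusted p = 0.0280 and 0.624) and did not pass without diabetic replicate 1 (0.209), PRP replicate 1 (0.0597) or PRP replicate 2 (0.0764), nor with the epithelial covariate (0.0775). Oxidative phosphorylation genes were lower with PRP (median -0.28, 26 of 27 lower, adjusted p = 0.000445 and 0.684) and did not pass without diabetic replicate 3 (0.0629). Adjusted over the list alone, 2 Schwann cell genes and 0 genes of the other 8 lists passed. Leaving out single libraries also moved medians that kept passing. Without diabetic replicate 1 they were 0.79 for fibroblast, 0.92 for repair macrophage, 0.42 for dendritic and 0.57 for Schwann cell genes, and without PRP replicate 2 that of the pro-inflammatory macrophage list was 0.19 (adjusted p = 0.0388). With the epithelial covariate the medians were 0.39 for neutrophil and 0.28 for pro-inflammatory macrophage genes. At a pseudocount of 0.1 they were 1.44 for neutrophil, 0.80 for pro-inflammatory macrophage and 0.56 for dendritic cell genes. The other 24 lists did not pass, among them hair follicle (median -0.93, all 29 lower, adjusted p = 0.0765), platelet (0.44, adjusted p = 0.0848) and growth factor genes (0.03, adjusted p = 0.684). Some of them gained a call in an alternative. Hair follicle genes passed as lower without non-diabetic replicate 2 (adjusted p = 0.00853), 3 (0.0169) or 1 and 3 (0.00288), without diabetic replicate 1 (median -2.17, adjusted p = 5.51e-05) or PRP replicate 1 (-1.52, adjusted p = 0.0408), with size factors (0.0168) and with a replicate block (0.0363). Skeletal muscle genes (-0.51, adjusted p = 0.103) passed as lower without non-diabetic replicate 1 (0.00748) or 1 and 3 (0.00871), without diabetic replicate 2 (0.0417) or 3 (0.00555), and with size factors (0.0451). Without diabetic replicate 1, endothelial (0.39, adjusted p = 0.000147), platelet (0.63, adjusted p = 0.0166) and myofibroblast genes (0.26, adjusted p = 0.0190) passed as higher and cell proliferation genes (-0.60, adjusted p = 4.90e-07) as lower. Without diabetic replicate 2, interferon (-0.38, adjusted p = 0.000195), mast cell (-0.37, adjusted p = 0.0221) and ribosomal protein genes (-0.22, adjusted p = 0.00786) passed as lower and basal keratinocyte genes (0.37, adjusted p = 0.0417) as higher. Without diabetic replicate 3, interferon genes passed as higher (0.27, adjusted p = 0.0213), and mitochondrially encoded (-0.47, adjusted p = 0.00274), adipocyte (-0.37, adjusted p = 0.0291) and insulin genes (-0.31, adjusted p = 0.0305) as lower. Without PRP replicate 1, endothelial (0.22, adjusted p = 0.0282), platelet (0.66, adjusted p = 0.0408), erythroid (0.25, adjusted p = 0.0408) and hypoxia genes (0.14, adjusted p = 0.0252) passed as higher and ribosomal protein genes (-0.26, adjusted p = 0.0253) as lower. Adipocyte genes also passed as lower without PRP replicate 2 (0.0488) and with a replicate block (0.0441), erythroid genes as higher with a filter at 1 FPKM (0.0313) and sebocyte genes as higher with the epithelial covariate (0.0271).

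Between diabetic ulcers with PRP and non-diabetic ulcers, keratinocyte and sebocyte lists rose and endothelial, fibroblast and interferon lists fell in camera with its preset correlation, while no list passed with an estimated correlation (smallest adjusted p = 0.645). In limma 1 gene passed, the snoRNA gene AC105648.6 (ENSRNOG00000055845, chromosome 8, 12163042 to 12163111). Its level was 0.567 ± 0.144 FPKM in non-diabetic, 1.37 ± 0.489 in diabetic and 8.23 ± 1.60 in PRP ulcers (SD, n = 3 each), a log2 change of 2.55 between PRP and non-diabetic ulcers (SE 0.20, adjusted p = 0.00986). It was also the 1 gene that differed in the F test over the 3 groups (adjusted p = 0.0249, 4117 genes with an unadjusted p under 0.05). The F test called 0 genes without non-diabetic replicate 1 or 3 or PRP replicate 2 or 3, 2 without diabetic replicate 2, 826 without diabetic replicate 1 and 1409 without non-diabetic replicate 2. The feature is 70 bases long, it passed in 13 of 20 alternatives, and the 355 tested snoRNA genes had a median log2 change of -0.07. Short noncoding features took 49.9% to 52.8% of the FPKM in the PRP libraries and 39.2% to 44.9% in the other 6. The log2 change was 2.58 with size factors (adjusted p = 0.00662) and 2.51 under quantile normalization (adjusted p = 0.0135), and over the 20 alternatives its adjusted p ran from 0.000154 to 0.622. An unadjusted p under 0.05 was reached by 3182 genes. The groups did not overlap in 29.4% of genes, where chance gives 10% on average, with a spread that was not computed. The next genes by p, which the rule names although they did not pass, were the natriuretic peptide clearance receptor gene Npr3 (1.79, adjusted p = 0.0659), the metalloreductase gene Steap1 (-1.65, adjusted p = 0.0659), the secretogranin gene Scg2 (-1.80, adjusted p = 0.128), the chemokine receptor gene Ccr2 and the B cell gene Cd22 (-1.27, adjusted p = 0.143). Ccr2 (ENSRNOG00000063127, chromosome 8, 123734430 to 123742100) stood at 26.4 ± 3.55 FPKM in non-diabetic and 6.37 ± 0.757 FPKM in PRP ulcers (adjusted p = 0.143). The count of genes was 0 without non-diabetic replicate 1, non-diabetic replicate 3 or PRP replicate 2, 2 without PRP replicate 1 or 3, 5 without diabetic replicate 2, 21 without diabetic replicate 1 and 714 without non-diabetic replicate 2. It was 6474 with sample weights, 2 with no filter and 0 on only the 6 libraries compared, with the epithelial covariate and without non-diabetic replicates 1 and 3, while edgeR called 41 and DESeq2 50 of the 249 deposited lncRNA genes. All 249 had been chosen by the authors for an unadjusted p under 0.05 between diabetic and these same non-diabetic libraries, so these counts are raised by the choice and not comparable with 1 of 15600.

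For PRP against non-diabetic ulcers 23 lists passed, 12 higher and 11 lower, and none passed with an estimated correlation (smallest adjusted p = 0.645) or in fry (smallest adjusted p = 0.243). No member of them passed over all genes. Lists that passed in all 16 alternatives, in which the covariate does not test the 2 keratinocyte lists, were cornified keratinocyte (median 2.42, adjusted p = 1.39e-06, 6 of 13 adjusted over the list alone), basal keratinocyte (1.14, adjusted p = 6.88e-06, 1 of 12), sebocyte (2.12, adjusted p = 6.28e-07, 11 of 12) and lipid synthesis genes (0.88, adjusted p = 6.88e-06, 9 of 21) on the higher side. On the lower side they were endothelial (median -0.89, adjusted p = 3.57e-06, 8 of 16), fibroblast (-0.93, adjusted p = 0.000136, 3 of 17), interferon (-0.54, adjusted p = 0.000676, 2 of 20) and immediate early genes (-0.90, adjusted p = 0.00617, 6 of 19). With an estimated correlation these 8 lists had an adjusted p of 0.645. Leaving out non-diabetic replicates 1 and 3 left 1 non-diabetic library. The medians were then 1.16 for cornified keratinocyte, 0.50 for basal keratinocyte, 0.50 for sebocyte, 0.34 for lipid synthesis, -0.51 for endothelial and -0.41 for immediate early genes. With the epithelial covariate, which holds the 2 keratinocyte lists and does not test them, they were 1.15, 0.44, -0.42 and -0.48 for the last 4 lists in that order. Without non-diabetic replicate 3 alone they were 1.28 for cornified and 0.72 for basal keratinocyte genes, and at a pseudocount of 0.1 that of sebocyte genes was 3.20. Krt5 stood at 576 ± 573 FPKM in non-diabetic and 1789 ± 618 FPKM in PRP ulcers, and Pecam1 at 63.4 ± 18.0 and 30.1 ± 10.3 FPKM.

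The other 15 lists that passed for PRP against non-diabetic ulcers lost the call in at least 1 alternative. Hair follicle (median 2.37, adjusted p = 4.75e-06) and skeletal muscle genes (1.53, adjusted p = 8.23e-05) had medians of -0.79 and 0.00 without non-diabetic replicates 1 and 3. Macrophage (-0.73, adjusted p = 0.00179), pro-inflammatory macrophage (-0.87, adjusted p = 0.00139) and repair macrophage genes (-0.83, adjusted p = 0.00576) did not pass without those 2 libraries (adjusted p = 0.0537, 0.938 and 0.319). Oxidative phosphorylation genes (0.33, adjusted p = 3.16e-05) did not pass there either (0.262). Matrix remodelling genes (-0.76, adjusted p = 0.00653) did not pass without PRP replicate 1 (0.146). Matrix genes (-0.53, adjusted p = 0.0310) did not pass without non-diabetic replicate 1 (0.0987), non-diabetic replicate 3 (0.0928) or PRP replicate 1 (0.522), and the median of matrix remodelling genes was 0.05 without both of the former. Cytokine genes (-0.87, adjusted p = 0.0322) did not pass without non-diabetic replicate 1 (0.0582) or 3 (0.638), diabetic replicate 2 (0.0579), or PRP replicate 1 (0.433) or 3 (0.101), nor with a filter at 1 FPKM (0.0616), and their median was 0.42 (adjusted p = 0.00574) without non-diabetic replicates 1 and 3. Wound-edge keratinocyte genes (1.28, adjusted p = 0.00139) did not pass without non-diabetic replicate 2 (0.104), growth factors (-0.35, adjusted p = 0.0296) without PRP replicate 1 (0.0752), and Schwann cell genes (0.47, adjusted p = 0.00852) without PRP replicate 3 (0.0543). Mitochondrially encoded genes (0.30, adjusted p = 0.0215) did not pass without non-diabetic replicate 2 (0.204) or PRP replicate 1 (0.0666) or under quantile normalization (0.0647), and ribosomal protein genes (0.31, adjusted p = 0.00139) did not pass under quantile normalization (0.0540). Adipocyte genes (0.39, adjusted p = 0.0434) did not pass without non-diabetic replicate 1 (0.142) or 3 (0.157), PRP replicate 1 (0.105) or 2 (0.0647), or with size factors (0.0719) or quantile normalization (0.0955). In camera with the epithelial covariate, macrophage (0.162), pro-inflammatory (0.402) and repair macrophage (0.450), matrix (0.796) and matrix remodelling genes (0.947) did not pass. Nor did cytokine (0.450), growth factor (0.534), adipocyte (0.531) and ribosomal protein genes (0.172). Without non-diabetic replicates 1 and 3 the medians of growth factor and ribosomal protein genes were -0.25 and 0.04. Medians of lists that kept passing moved as well. Without non-diabetic replicate 2 they were 4.01 for hair follicle, 2.55 for skeletal muscle, -1.32 for matrix remodelling, -1.47 for cytokine and 0.51 for oxidative phosphorylation genes. Without non-diabetic replicate 3 they were 0.94 for hair follicle and -0.34 for matrix remodelling genes (adjusted p = 0.0485), and without non-diabetic replicate 1 that of skeletal muscle genes was 0.44 (adjusted p = 0.0252). Without PRP replicate 2 the wound-edge keratinocyte median was 0.36 (adjusted p = 0.0427), and without PRP replicate 1 that of ribosomal protein genes was 0.18. Without PRP replicate 3 they were -0.88 for matrix, 0.59 for adipocyte and 0.49 for mitochondrially encoded genes. With the epithelial covariate they were 0.37 for wound-edge keratinocyte and 0.17 for oxidative phosphorylation genes, and at a pseudocount of 0.1 that of Schwann cell genes was 1.03. Adjusted over the list alone, 3 pro-inflammatory macrophage and 2 matrix remodelling genes passed, and 0 of the other 13 lists. With an estimated correlation the adjusted p was 0.728 for matrix and cytokine genes, 0.654 for ribosomal protein genes and 0.645 for the other 12 lists. Of the lists without a call, neutrophil genes (-1.15, adjusted p = 0.128) passed as lower without non-diabetic replicate 2 (-1.86, adjusted p = 0.000526) or PRP replicate 2 (0.00148) and as higher without non-diabetic replicates 1 and 3 (0.34, adjusted p = 0.00106). T and NK cell genes (-0.24, adjusted p = 0.536) passed as lower without non-diabetic replicate 2 (0.0302) and as higher without non-diabetic replicates 1 and 3 (0.29, adjusted p = 0.00159) and with the epithelial covariate (0.00541). B and plasma cell genes (-0.28, adjusted p = 0.190) passed as lower without non-diabetic replicate 2 (0.0308) or PRP replicate 2 (0.0125). Platelet genes (-0.54, adjusted p = 0.0545) passed as lower without non-diabetic replicate 2 (0.0362), diabetic replicate 1 (0.0425) or 2 (0.0458) or PRP replicate 3 (0.0387), with size factors (0.0446) and under quantile normalization (0.0476). Cell proliferation genes (0.12, adjusted p = 0.0940) passed as higher without non-diabetic replicate 2 (0.0486) or 3 (0.0319) or diabetic replicate 1 (0.0388). Without non-diabetic replicate 2, Wnt (0.0302) and replication-dependent histone genes (0.0412) passed as higher, and with the covariate mast cell genes did (0.00991).

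The comparisons were then set side by side for the genes that differed between diabetic and non-diabetic ulcers. No gene was called in opposite directions by diabetes and by PRP in limma, as PRP called 0 genes. Of the 279 genes higher in diabetic ulcers, 256 (91.8%) had a lower mean log2 level with PRP, and in 255 the PRP mean lay between those of the other groups. Their median log2 change was 1.04 with diabetes and -0.36 with PRP. Of the 1117 genes lower in diabetic ulcers, 1073 (96.1%) had a higher level with PRP, and 1069 lay between, with medians of -1.23 and 0.43. Sfrp2, for example, stood at 21.9 ± 18.3 FPKM with PRP, between 4.92 FPKM in diabetic and 79.0 FPKM in non-diabetic ulcers. Both comparisons use the same diabetic libraries with opposite sign, so genes chosen for a difference in 1 of them move back in the other by construction. In simulated unchanged groups, of the 279 highest and 1117 lowest genes by p a median of 95.3% and 91.9% had the opposite sign with PRP (0% to 100% and 1.07% to 100%), and 63 and 34 of 100 draws were as high as the observed shares. The shares thus do not separate an effect of PRP from no change. Across genes, which are not independent replicates, the fold changes had a correlation of -0.654, where simulated unchanged groups gave -0.478 on average (-0.949 to 0.796, 37 of 100 draws as low). Their covariance was -0.225, where the simulation gave -0.0683 (-0.327 to 0.0329, 7 of 100 draws as low), an excess of -0.157 from which the mean effect of sharing is already taken out. Single draws lay further from that mean than the observed value, so the whole excess can come from chance values of the shared libraries, 3 being too few to split.

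The authors' deposited comparison of diabetic with non-diabetic ulcers lists 249 lncRNA genes, of which 171 were higher and 78 lower in diabetic ulcers. By the authors' adjusted p, 64 of the higher and 44 of the lower genes were below 0.05. All 249 had the same sign in the FPKM table. The lists were chosen by the authors on these libraries and are not independent evidence of direction. Among the higher genes, 48 had a count of 0 in all 3 non-diabetic libraries in the authors' table. The genes with the smallest adjusted p in the authors' table, named after their values were seen, include ENSRNOG00000066887 (chromosome 1, 38624474 to 38691338), with deposited mean scaled counts of 41.5 in diabetic and 597 in non-diabetic ulcers (log2 change -3.84, adjusted p = 8.19e-07). On the higher side they include ENSRNOG00000064284 (chromosome 2, 31484118 to 31489995), with deposited means of 1187 and 215 (2.47, adjusted p = 2.98e-06). On the counts of the 249 deposited genes edgeR called 160 and DESeq2 139 for diabetic against non-diabetic ulcers, the comparison the genes were chosen by.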

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

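Of the alternatives here, the epithelial score as a covariate, non-diabetic replicates 1 and 3 both left out, and edgeR with depths from the FPKM were chosen after seeing the data. The count of genes for diabetic against non-diabetic ulcers (1396) was 0 with no filter, where 24362 features were tested and the smallest adjusted p was 0.0548. It was 861 with size factors, 5607 with sample weights, 893 with a minimum absolute log2 change of 1, which removes genes by construction, and 0 on only the 6 libraries, with the epithelial covariate and without non-diabetic replicates 1 and 3. On the 249 genes of the count table edgeR called 160, DESeq2 139 and edgeR with depths from the FPKM 208, where fewer genes were tested, all chosen by the authors for a difference in this comparison. Leaving out 1 library gave 0 to 3501. With PRP against diabetic ulcers (0) the count was 1 with no filter, 1 with size factors, and 0 with each library left out. With PRP against non-diabetic ulcers (1) it was 2 with no filter, 6474 with sample weights, 0 on only the 6 libraries, with the epithelial covariate and without non-diabetic replicates 1 and 3, 41 in edgeR, 50 in DESeq2, 48 in edgeR with depths from the FPKM, and 0 to 714 with 1 library left out. Among the 3 groups (1) it was 0 at a pseudocount of 0.1, 6824 with sample weights, 0 with the epithelial covariate and without non-diabetic replicates 1 and 3, 97 in edgeR, 93 in DESeq2, 98 in edgeR with depths from the FPKM, and 0 to 1409 with 1 library left out. In the weighted fits non-diabetic replicate 1 had a weight of 7.495, next to 0.482 and 0.827 for the other non-diabetic libraries. Where no construction is named, the cause was not tested. Same-numbered libraries had residual correlations of -0.407 to 0.351, with 3 of 9 pairs above 0.1, so the replicate numbers were not taken as a pairing. With the replicate number as a block the counts were 1259, 0 and 0 for the 3 comparisons and 0 among the 3 groups. No gene was called in opposite directions for diabetes and PRP in any alternative run (0 to 0 over libraries left out), which the 0 or 1 genes called with PRP leave little room for. The lists passing (26, 16 and 23) were 0, 0 and 0 with an estimated correlation and 0, 0 and 0 in fry, and those for PRP against non-diabetic ulcers were 14 without non-diabetic replicates 1 and 3. With 1 library left out 24 to 28, 14 to 20 and 17 to 28 lists passed. Of 320 values of the genes named for diabetic against non-diabetic ulcers, 141 kept their side of the threshold and 179 no longer passed, of 100 for PRP against diabetic ulcers all 100 kept it, and of 100 for PRP against non-diabetic ulcers 82 kept it and 18 newly passed. None changed direction. Genes at low FPKM cannot be given a counting error, since the count table used covers 249 genes.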

Other observations

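The tests of dilution by epidermis, of the share of epithelium, of library scores without diabetic replicate 2, and those on Fam111a were chosen only after the result was seen. Several lists with no call for diabetic against non-diabetic ulcers held single genes that passed. In hypoxia and glycolysis (median log2 change -0.38, adjusted p = 0.272), Hif1a, the oxygen-regulated transcription factor, fell from 128 ± 71.6 to 35.1 ± 4.80 FPKM (SD, n = 3 each) and Egln3, a hydroxylase that acts on it, rose from 5.50 ± 2.19 to 17.0 ± 4.35 FPKM, with 3 genes higher and 5 lower adjusted over the list alone. In Wnt and hedgehog signalling (0.54, adjusted p = 0.229) the secreted Wnt modulators Sfrp4 (-2.71), Sfrp2 (-3.79) and Dkk3 (-1.09) fell, with 2 higher and 3 lower adjusted over the list alone. In dendritic and Langerhans cells (-0.48, adjusted p = 0.0647, and 0.0453 with a replicate block, as lower) the antigen presentation gene Cd74 (-2.16) and Itgax (-2.37) fell, with 2 higher and 4 lower adjusted over the list alone. In mast cells (0.44, adjusted p = 0.126, and 0.00805 without diabetic replicate 2 and 0.00872 with the epithelial covariate, as higher) the IgE receptor gene Fcer1a rose (0.61) and the IL-33 receptor gene Il1rl1 fell (-2.29), with 3 higher and 1 lower adjusted over the list alone. The insulin list (0.14, mean 0.02, tested as lower, adjusted p = 0.897) held Hk1 (-0.57) and Pck2 (-0.78), which fell, with 3 lower adjusted over the list alone. The oxidative stress list (-0.06, mean 0.01, adjusted p = 0.991) held the heme oxygenase gene Hmox1 (-2.08), and the erythroid list (-0.11, adjusted p = 0.488) the hemoglobin gene Hba-a2 (-2.45), each fallen and the 1 gene adjusted over the list alone. Myl9 (-0.94) fell in the myofibroblast and smooth muscle list (-0.22, mean 0.04, adjusted p = 0.596) and Mal (-1.46) in the Schwann cell list (0.44, adjusted p = 0.682), each the 1 gene adjusted over the list alone. Pdpn fell from 72.3 ± 23.4 to 18.4 ± 9.72 FPKM in the lymphatic endothelial list (-0.50, adjusted p = 0.181), with 1 higher and 1 lower adjusted over the list alone. No member passed, over all genes or adjusted over the list alone, in cell proliferation (0.24, adjusted p = 0.0795), wound-edge keratinocyte (0.06, adjusted p = 0.536), unfolded protein response (-0.14, adjusted p = 0.187) and replication-dependent histone genes (0.82, adjusted p = 0.0904). Of these, cell proliferation genes passed as higher without diabetic replicate 1 (0.72, adjusted p = 4.71e-06) or non-diabetic replicate 3 (0.0282), histone genes without diabetic replicate 1 (1.47, adjusted p = 0.0299) or non-diabetic replicate 2 (0.0370), and wound-edge keratinocyte genes without non-diabetic replicates 1 and 3 (0.63, adjusted p = 0.00143). The sex-linked list, with 2 tested members, was not tested. Among lists without a call, median, mean and test also differed in sign for PRP against diabetic ulcers in the myofibroblast, cornified keratinocyte, lipid synthesis, oxidative stress, immediate early and Wnt lists, and for PRP against non-diabetic ulcers in the dendritic, erythroid, oxidative stress and unfolded protein response lists.

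Of 5 microRNA genes on chromosome X (132801380 to 132806688), named after their values were seen, 3 passed as lower in diabetic than in non-diabetic ulcers. Mir503-2 fell from 3.27 ± 2.63 to 0.103 ± 0.0929 FPKM (log2 change -1.78, adjusted p = 0.0388), Mir351-2 from 2.33 ± 1.10 to 0.191 ± 0.331 FPKM (-1.47, adjusted p = 0.0320) and rno-mir-450a from 0.901 ± 0.256 to 0.195 ± 0.104 FPKM (-0.66, adjusted p = 0.0380). The diabetic means of these 3 genes lie below 0.5 FPKM, the level of the filter, and cannot be given a counting error. In this comparison 0 genes of any kind were called without non-diabetic replicate 1 or 3. All 5 genes lie within 1 short stretch, so their calls may not be independent. Mir450b-2 was listed at 0 in all 3 diabetic libraries and did not pass (adjusted p = 0.0637). With PRP, Mir503-2 stood at 2.95 ± 1.11 and Mir351-2 at 1.20 ± 0.382 FPKM, neither passing against diabetic ulcers in limma (adjusted p = 0.713 each). Mir322-2 stood at 0.409 ± 0.373, 0.208 ± 0.0795 and 0.592 ± 0.499 FPKM in non-diabetic, diabetic and PRP ulcers (adjusted p = 0.626 for diabetic against non-diabetic).

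Epithelial, hair follicle and muscle lists were higher and matrix, fibroblast and macrophage lists lower in diabetic than in non-diabetic ulcers. Scaling between libraries is argued against, since the matrix median was -1.56 or further from 0 under size factors and quantile normalization. A dilution of every other cell type alike by epidermis would move muscle and fibroblast genes alike. The skeletal muscle score minus the fibroblast score differed by 3.62 (pooled SD 1.66). That difference is part of the pattern itself, so it cannot decide. Muscle scores also overlapped, at 3.56 to 7.43 in non-diabetic and 6.97 to 9.20 in diabetic libraries. A different share of epithelium in the pieces could account for part of the fall of macrophage genes, since with the epithelial score as a covariate their median was -1.10 in place of -1.60, and their mean level differed by -1.11 (SE 0.56) in place of -1.60 (SE 0.45), so whether more or less than 50% of the change remains lies within the error, and for these genes a share of epithelium and an effect of diabetes cannot be told apart. Without non-diabetic replicates 1 and 3 the median was -1.50, but this rests on 1 non-diabetic library. Its epithelial score of 5.46 lay below the 6.67 and 6.41 of diabetic replicates 2 and 3 and above the 4.46 of diabetic replicate 1. The share of epithelium thus still differed, and this value cannot decide. Diabetes itself, as the design names it, stays open.

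Matrix, macrophage and lymphocyte lists were higher with PRP while no gene passed in limma (0 genes, 1021 at an unadjusted p under 0.05, and 0 in edgeR and DESeq2). Diabetic replicate 2 was the library lowest in matrix and macrophage genes, and without it both lists still passed (higher adjusted p = 0.000195), which had been set in advance as the bound against it. That bound was wrong, as this p takes no account of the spread between libraries, and the matrix score then differed by 0.47 (SE 0.41, against 0.96 with all libraries) and the macrophage score by 0.58 (SE 0.38, against 0.98), so this library and an effect of PRP cannot be told apart. Correlation of the genes within a list may account for the calls, as the adjusted p of the matrix list was 0.624 with an estimated correlation, and the diabetic libraries shared by both comparisons may likewise account for the opposed fold changes, whose covariance of -0.225 lay inside the simulated range, with 7 of 100 draws as low. An effect of PRP stays open and was not separated from these.

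Fam111a was high in all 3 non-diabetic libraries (64.4 to 133 FPKM) and PRP replicate 1 (50.9 FPKM) and low in the other 5 (1.35 to 3.91 FPKM). The tissue makeup of the pieces stays open: 0 other genes showed this pattern at the gap of Fam111a itself (12.7-fold) or at 2-fold and 5 did at 1.5-fold, but the other 125 patterns of 4 high libraries also held a median of 0 genes at 2-fold and at 1.5-fold. An inherited difference between animals stays open too. Of 27 genes with such a gap, 14 were on in some and off in other libraries of the diabetic group and of another group. Fam111a was not among the 14, and the number to be found without such a difference was not computed, so the count cannot decide. The clearest of the 14 was ENSRNOG00000063015, at 0.0716 FPKM in non-diabetic replicate 3, 0.00672 FPKM in diabetic replicate 3 and 84.7 to 155 FPKM in the other 7 libraries. An effect of diabetes on Fam111a stays open.

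For the comparisons of 3 with 3 libraries, the 10 splits are too few for a share under 0.05. For diabetic against non-diabetic ulcers the real split gave 1396 genes and the highest other 1, so that 1 of 10 splits gave as many. For PRP against diabetic ulcers the real split gave 0 genes in limma (1021 at an unadjusted p under 0.05, and 0 in edgeR and DESeq2) and the highest other 2, with 10 of 10 splits giving as many. For PRP against non-diabetic ulcers the real split gave 1 and the highest other 3, with 4 of 10 giving as many. Among the 3 groups, 33 of 100 splits gave at least the 1 gene of the real split, so chance is not excluded there, and the highest other gave 393 genes, as a structure of the samples other than the groups would give, for which no test was run. Simulated unchanged groups had a median of 0 calls. For diabetic against non-diabetic ulcers 2 of 100 draws had any call, the highest 270, and 0 reached 1396. For PRP against diabetic ulcers, where the data gave 0 genes, 4 of 100 draws had any, the highest 394. Counts of 270 and 394 thus arose in single draws without an effect of the groups.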
